A study of Mus musculus with 2 samples.

How the data were processed

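Total RNA was extracted with Trizol from newly formed splenic B cells, flow sorted as B220-positive cells with high surface IgM, and biotin-labelled cRNA was hybridized to an Affymetrix array, per the labels' protocols. The labels disagree on some points. The cell type tag names pro B cells while the titles and the series design name newly formed B cells, and the control is described both as carrying 1 floxed allele with Cre and as wild type. Both samples come from mice aged 4 to 6 weeks. The groups were taken from the genotype tags, 1 sample in the control group and 1 in the deleted group.

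The deposited values are log2 expression values per probe set. MAS5 is the only tool the submitters' processing notes name, without a version, and the normalization between arrays is not given in the sources used here. MAS5 signals commonly scatter most at low level, whereas the SD of the log2 ratio was 0.17 in the dimmest of 10 equal bins of mean value and 0.16 in the brightest. The method that produced the values is therefore not settled, and ratios of dim probe sets depend on it. Each deposited log2 value is the authors' mean of biological replicates, per the labels, and the number of replicates is not stated. The authors' second table gives the same means, a ratio of control over deleted and a signed fold change score. The log base was found from the values, since the authors' deposited ratio equals 2 to the power of the difference of the log2 means, and the sample values of both tables are identical (largest difference 0). The deposited fold change score is the ratio where it is 1 or more and otherwise minus its inverse. Control log2 values ran from 1.93 to 13.6 with quartiles of 3.24 and 6.72, and those of the deleted group from 1.96 to 13.5 with quartiles of 3.19 and 6.70. The number of arrays behind each mean limits the precision and is unknown.

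From these values the log2 ratio, deleted minus control, was computed per probe set without further scaling, the opposite direction to the authors' deposited ratio. Of 45101 probe sets, 64 Affymetrix controls were set aside. The authors' table names 1 gene for 37463 of the others, several for 1460 and none for 6114. Symbols were updated through a RefSeq gene table of the GRCm38.p6 assembly, and 34464 of the 37463 matched (92.0%), 31566 by accession, 2104 by symbol and 794 by synonym, while 2999 kept the name in the file. No genome build is named in the sources used here, so no coordinates are given. A probe set counted as measured when its value was at or above the median (percentile 50) of its own sample in both samples, and each gene was represented by its measured probe set with the highest mean value. Differences between the probe sets of a gene are stated where they change a reading.

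No test across samples was possible with 1 sample per group, so no p-values or standard errors are given. Counts of probe sets use a threshold of 2-fold. The 26 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from the measured genes and matched in 10 bins of mean log2 value. A list with at least 5 measured members outside percentiles 2.5 to 97.5 was reported as outside the range, as a description of these 2 samples. The text names all probe sets of Chuk, the 12 genes with the largest ratios in each direction, up to 4 measured members of each list with the largest absolute ratio, and up to 5 genes per direction measured in 1 sample only. The globins, Mki67, Top2a, Cd1d1, Cd93 and the genes of the closing observations, Bpgm and Slc14a1 among them, were named after their values were seen.

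The calculations were tested on simulated data. For the comparison of deleted over control, over 21832 probe sets, 14% of 50 probe sets simulated with a log2 ratio of 0.8 passed 2-fold, 84% of 50 at 1.2 and 100% of 50 at 1.6 or at 2, and 0% of 21632 unchanged ones did. Among 11411 genes, 4.5% of 200 random lists of unshifted genes fell outside the range, and 100% of 50 lists shifted by 0.25 did. The simulated noise was normal and independent between probe sets, with the spread seen at each level. These percentages therefore check the calculations and are not error rates for the real counts or for lists of co-regulated genes. The alternatives were centring on the sample medians, quantile normalization, a loess fit of the ratio on the mean value (span 0.3), a pseudocount of 16 or 64 on the linear scale, no filter or a filter at percentile 75, thresholds of 1.5-fold and 3-fold, 1 probe set per gene, the mean of a gene's probe sets, probe sets without the cross-hybridizing suffixes, and the authors' deposited fold changes. Alternatives that need replicate columns (limma with or without a replicate block, leaving out replicates, camera) were not run. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.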

Results

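Gene expression was measured on an Affymetrix array in newly formed B cells, the immature B cells that reach the spleen from the bone marrow, sorted from spleens of mice aged 4 to 6 weeks. The series holds 2 samples, 1 per group. One group came from mice carrying floxed alleles of Chuk, the gene of the kinase IKK alpha in the non-canonical NF-kB pathway, together with Cre expressed from the Cd19 locus. The other came from control mice, which one label describes as carrying 1 floxed allele with Cre and another as wild type. Each value is the authors' mean of biological replicates whose number is not stated, so no spread between animals was available, no test was run and none of the differences has a replicate check. The comparison asks how expression in newly formed B cells, the precursors of marginal zone and follicular B cells, differs when Chuk is deleted in the B lineage. The array carried 45037 probe sets besides its controls, and 21832 of them, naming 11411 distinct genes where they named 1 gene, were measured, meaning at or above the median of their own sample in both samples. The median log2 value was 4.28 in the control sample and 4.18 in the other.

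Chuk itself was higher in the sample labelled deleted on all 3 of its probe sets. The log2 values were 8.96 in the control and 9.32 in the deleted-labelled sample on the brightest probe set, a difference of 0.35 on the log2 scale or 1.28-fold. The other probe sets were higher by 0.38, from 8.25 to 8.63, and by 0.11, from 7.59 to 7.70. All log2 ratios here are deleted-labelled over control, whereas the authors' deposited table gives control over deleted, with ratios of 0.782, 0.770 and 0.926 for the same probe sets. The sources used here give neither the deleted exons nor the positions of the probes. Probes outside the deleted part would check nothing, so the higher transcript level does not bear out the label and does not show it to be wrong. The second sample is therefore called the deleted-labelled sample throughout, and every direction below rests on that label.

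The 12 genes with the largest positive ratios in the deleted-labelled sample were led by Efhd2, a calcium-binding regulator of the actin cytoskeleton. It was higher by 1.40 on the log2 scale (2.63-fold), and by 0.88 on its other measured probe set. Rsad1 was 2.58-fold higher, the glycosyltransferase gene B4galnt2 2.28-fold and 1700007L15Rik 2.28-fold. Rgs13, a regulator of G protein signalling known from germinal centre B cells, was higher by 1.16, from 4.78 to 5.95. Gad1, the glutamate decarboxylase gene, was higher by 1.13 and Tbc1d7, a subunit of the tuberous sclerosis complex, by 1.08. Cdk5rap1, Cip2a and the interferon-inducible family member Ifit1bl1 were higher by 0.98, 0.96 and 0.96. Znf41-ps and BC147527 were higher by 0.90 each, although the measured probe sets of Znf41-ps ranged from 0.07 to 0.90.

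The 12 genes with the largest negative ratios were led by Serpine2, a secreted serine protease inhibitor, which was 2.59-fold lower (log2 ratio -1.38). Eps8l1, a relative of the actin regulator Eps8, was 2.58-fold lower. Dhrs3, a retinal reductase, was 2.43-fold lower, and Tsga13 was 2.15-fold lower. Cap1, a cyclase-associated protein that turns over actin filaments, had ratios of -1.05 and -0.97 on both of its probe sets. Ly6k had a ratio of -1.03, and Pla2g7, which degrades platelet-activating factor, had log2 values of 5.29 in the control and 4.29 in the deleted-labelled sample. Asb2, a ubiquitin ligase subunit and one of the marginal zone markers, was 1.93-fold lower (-0.95). The ratios of Endod1 and A130040M12Rik were both -0.91 on the brightest probe set, with ranges of -0.91 to -0.18 and -1.26 to -0.91 over their measured probe sets. Probe sets disagreed in sign for the nuclear long noncoding RNA Malat1, whose 7 ratios ran from -1.16 to 0.038, with 4 at least 2-fold lower. They also did for Trp53, with -0.94 and -0.79 on its brighter measured probe sets and 0.090 on its dimmest.

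Across all measured probe sets, 9 were at least 2-fold higher and 25 at least 2-fold lower in the deleted-labelled sample, and 98.1% lay within 1.5-fold. After both samples were centred on their median log2 value the split was 12 higher and 12 lower, and counting 1 probe set per gene it was 7 genes higher and 8 lower. Without the filter on low values, the authors' deposited table holds 13 probe sets at least 2-fold higher in the deleted group and 37 at least 2-fold higher in the control.

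**Figure D1:**
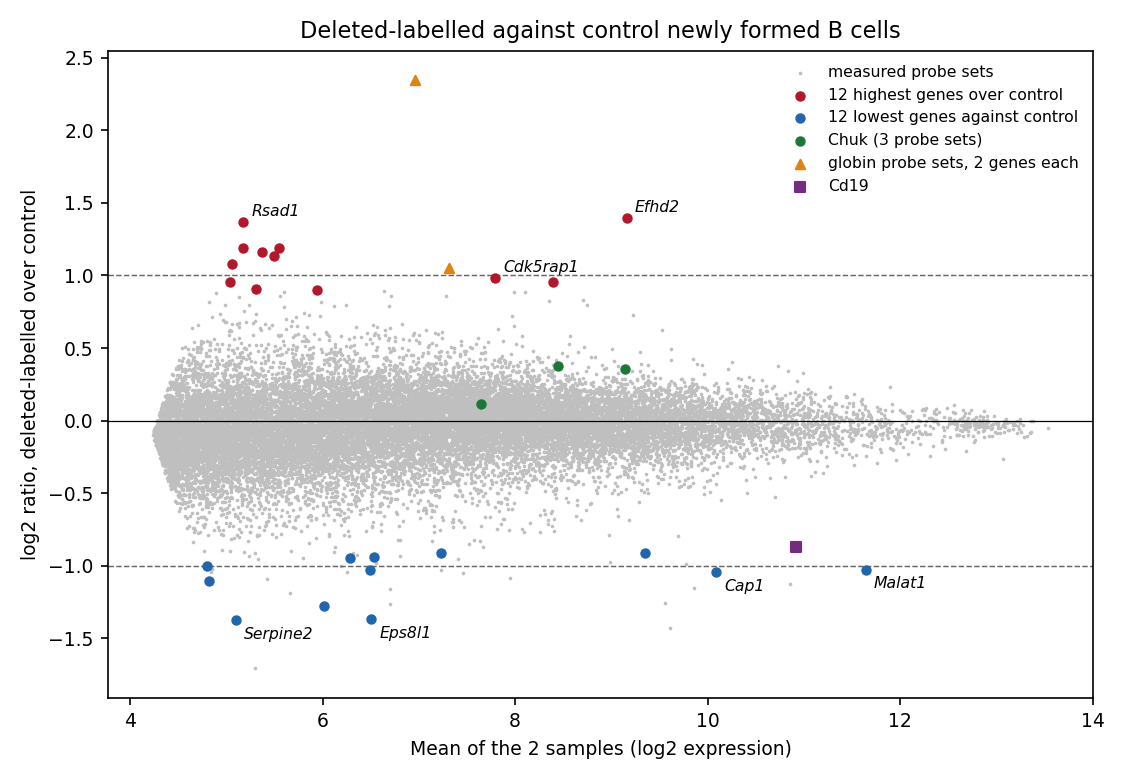
Log2 ratio (deleted-labelled over control) against the mean log2 expression of both samples, 1 point per measured probe set, with dashed lines at 2-fold. The 3 Chuk probe sets lie above 0, at 0.11 to 0.38, and Cd19 lies at -0.87 among probe sets of similar level that mostly stay close to 0.

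Some genes passed the level criterion in 1 sample and not in the other, and for them only a lower bound of the fold is given, the brighter value against the other sample's median. S100a8 and S100a9, abundant granulocyte proteins, were at least 4.32-fold and at least 2.92-fold lower in the deleted-labelled sample. Grap2 and Cd7, both expressed in T cells, were at least 1.52-fold and at least 1.49-fold lower, and Tcaf1 at least 1.47-fold lower. In the other direction Mid1, a microtubule-associated ubiquitin ligase, was at least 1.97-fold higher. Ear2 was at least 1.64-fold higher, the fatty acid binding protein gene Fabp5 at least 1.56-fold, Zfp458 at least 1.53-fold and Rwdd3 at least 1.45-fold. Globin transcripts were also higher, a feature picked out after its values were seen. Of the 3 probe sets shared by the alpha globin genes Hba-a1 and Hba-a2, the 1 measured in both samples was higher by 2.35, from 5.79 to 8.14, and the others were at least 3.84-fold and at least 14.7-fold higher, reaching a log2 level of 8.16. The probe set shared by the beta globin genes Hbb-b1 and Hbb-b2 was higher by 1.05, from 6.79 to 7.84.

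Cell cycle genes were higher as a group in the deleted-labelled sample. Of 33 measured members, 29 were higher and 4 lower, 13 were at least 1.5-fold higher, and the median log2 ratio was 0.48 (SD across genes 0.30). None of 10000 random lists matched on expression level had a median as high, and the middle 95% of those medians ran from -0.081 to 0.064. The mitotic kinesin Kif11 was higher by 0.86 on its brightest probe set and by 0.38 on its lowest. Birc5, which encodes survivin of the chromosomal passenger complex, was higher by 0.82, the mitotic kinase gene Plk1 by 0.76 and the spindle checkpoint kinase gene Bub1 by 0.74. Among members picked after their values were seen, the proliferation marker Mki67 was higher by 0.55, from 7.60 to 8.14. The DNA topoisomerase gene Top2a was higher by 0.72, with its probe sets between 0.14 and 0.72. The list's median was 0.22 with a pseudocount of 64 and 0.19 when only genes above percentile 75 in both samples were kept. The globin transcripts were higher in the same sample, by 1.05 and 2.35 on their measured probe sets. The other 4 measured erythroid markers, too few to place, had a median ratio of 0.15. Without the level filter the erythroid list had a median of 0 at percentile 74.2. S100a8 and S100a9 were lower by at least 4.32-fold and at least 2.92-fold, and the 3′ minus 5′ difference of the poly-A spike-ins, a measure of labelling, was larger in that sample for 8 of 8 pairs, by a median of 0.22. Each spike-in transcript is covered by more than 1 of these pairs.

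Interferon-stimulated genes had a median ratio of 0.14, at percentile 99.99 of the matched random lists, with 19 of 24 measured members higher and 5 lower. Ifit2, Ifit3 and Rsad2, antiviral effector genes induced by interferon, were higher by 0.51, 0.47 and 0.44. The largest single ratio in the group ran the other way, with Oasl2 1.70-fold lower (-0.76). After centring both samples on their medians the list's median was 0.24. Mitochondrial respiration genes showed a small uniform difference on their brightest probe sets, with all 22 measured members higher and a median of 0.11, above every matched random list. Other probe sets differed, with the lowest of Cox5b at -0.26, of Atp5c1 at -0.22 and of Atp5a1 at -0.0059. With the mean of each gene's probe sets the median was 0.095. The ATP synthase gene Atp5o was higher by 0.20. The complex I genes Ndufs3 and Ndufa2 were higher by 0.19 and 0.18, and the cytochrome oxidase gene Cox7a2 by 0.17. After centring, the median of the mitochondrial list was 0.21. In the same sample the measured globin probe sets were higher by 1.05 and 2.35, and S100a8 and S100a9 were lower by at least 4.32-fold and at least 2.92-fold. Lyz1 and Lyz2 were higher in that sample by 0.59 and 0.38, but 8 of the 11 measured myeloid markers were lower. The poly-A spike-in 3′ minus 5′ difference was larger there by a median of 0.22. It is a contrast within transcripts and cannot be ranked against a list's median ratio.

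Marginal zone B cell markers were lower as a group in the deleted-labelled sample. Of 21 measured members 19 were lower and 2 higher, 3 were at least 1.5-fold lower, and the median log2 ratio was -0.22 (SD across genes 0.30), below every matched random list. After centring both samples on their medians, 13 of the 21 were lower and the list's median was -0.13. After quantile normalization and after loess 18 of the 21 were lower, with a median of -0.19 each. Beside Asb2, the sphingosine phosphate receptor gene S1pr3, which helps position marginal zone B cells, was 1.74-fold lower. The tetraspanin gene Cd9 was 1.57-fold lower, and Tm6sf1 was 1.42-fold lower. Cd1d1, the lipid-presenting molecule that is high on marginal zone B cells, was picked out after its value was seen and was 1.41-fold lower, from 10.66 to 10.16. Follicular B cell markers stayed inside the matched random range, with 6 of 13 higher and a median of -0.030. Fcer2a, the gene of the follicular marker CD23, was higher by 0.28 and Sell, the gene of L-selectin, by 0.19. The complement receptor gene Cr2, which stands in both lists, had a ratio of -0.22, and the complement regulator gene Cd55 had -0.20. In the same sample S100a8 and S100a9 were lower by at least 4.32-fold and at least 2.92-fold, and globin transcripts were higher by 1.05 and 2.35 on their measured probe sets. The lysozyme genes Lyz1 and Lyz2 were higher in that sample by 0.59 and 0.38, but 8 of the 11 measured myeloid markers were lower. The poly-A spike-in 3′ minus 5′ difference was larger there by a median of 0.22.

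Genes of B cell identity and receptor signalling had a median ratio of -0.10, at percentile 0.05 of the matched random lists, with 23 of 26 measured members lower. After centring on the sample medians 15 of 26 were lower and the median was -0.0081. Centring moves the matched random lists by the same amount, so the percentile stayed at 0.05. After quantile normalization and after loess 22 of 26 were lower, with medians of -0.076 and -0.067. Cd19, the coreceptor gene whose locus carries the Cre, was 1.83-fold lower on its 1 probe set, from 11.36 in the control to 10.48. It stood far from the brightest probe sets of the rest. Over all measured probe sets the rest ran from -0.77 (Vav2) to 0.25 (Pik3cd). The transcription factor gene Ebf1 had a ratio of -0.29 and the inhibitory Fc receptor gene Fcgr2b a ratio of -0.27. Pik3cd, the lymphocyte PI3-kinase gene, had -0.25 on its brightest probe set, while its probe sets ranged from -0.37 to 0.25. Germinal centre and plasma cell genes had a median of -0.26, below every matched random list, with 12 of 14 lower. It was -0.17 after centring, with 10 of 14 lower, and -0.096 with a pseudocount of 64. After quantile normalization and after loess it was -0.19, with 12 of 14 lower. The array's Ighg entry had a ratio of -0.42, the joining chain gene Jchain -0.36, the plasma cell regulator gene Prdm1 -0.33 and Mef2b -0.30. The same sample had the lower S100a8 and S100a9 bounds of 4.32-fold and 2.92-fold and the measured globin ratios of 1.05 and 2.35. Lyz1 and Lyz2 were higher there by 0.59 and 0.38, but 8 of the 11 measured myeloid markers were lower. The poly-A spike-in 3′ minus 5′ difference was larger by a median of 0.22.

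**Figure D2:**
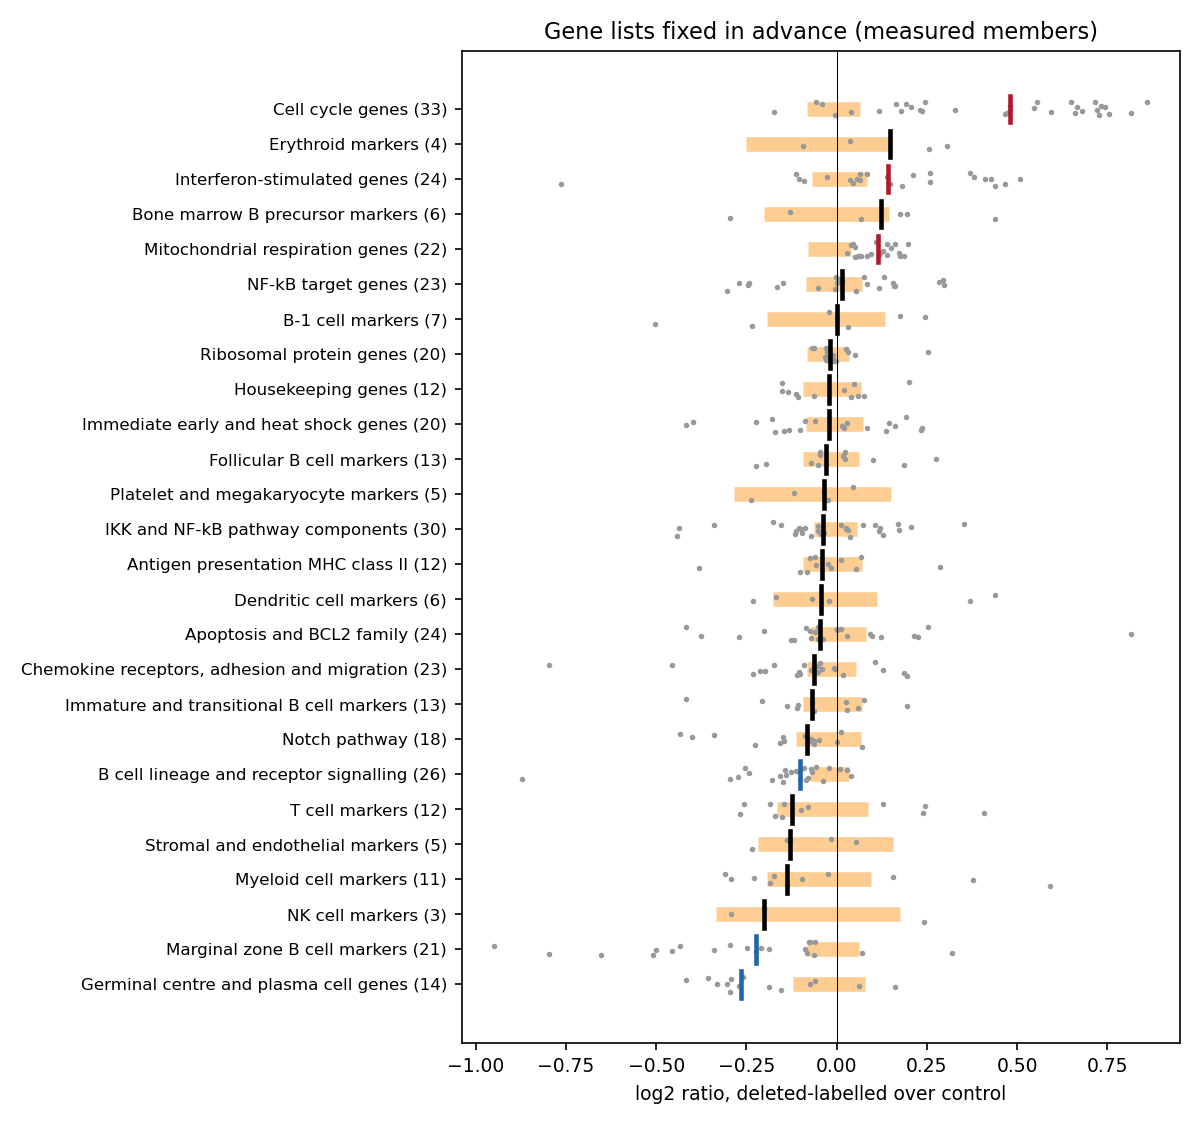
Log2 ratio (deleted-labelled over control) of the measured members of each of the 26 gene lists, with the number of members in brackets, grey points for genes, vertical bars for the list median and orange bands for the middle 95% of medians of 10000 random lists matched on level. Red medians (3 lists) lie above and blue medians (3 lists) below their bands, from 0.48 for cell cycle genes to -0.26 for germinal centre and plasma cell genes.

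**Figure D3:**
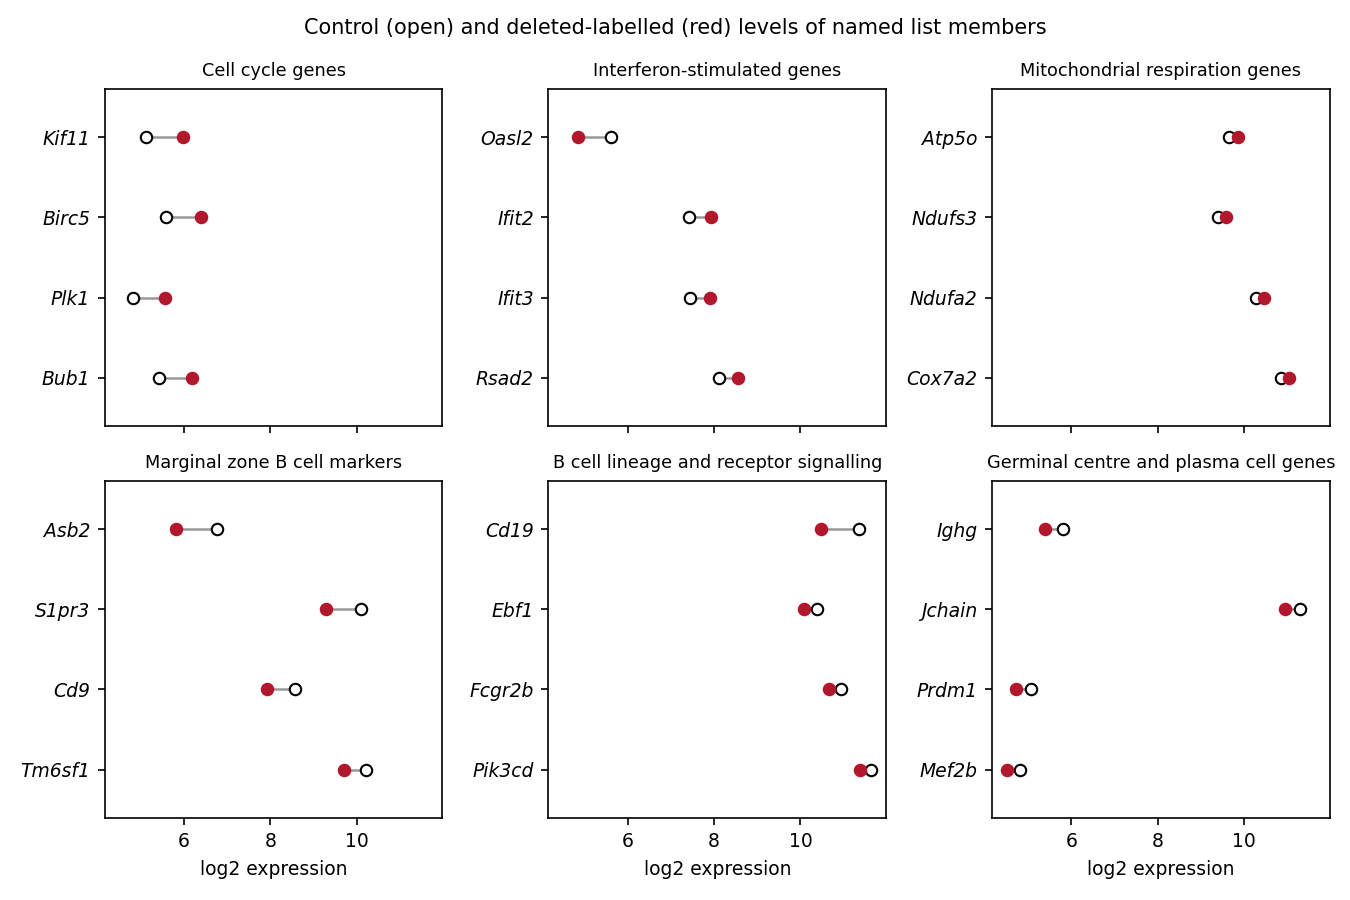
Log2 expression in the control sample (open) and the deleted-labelled sample (red) for the 4 members with the largest absolute ratio in each of the 6 lists that lay outside the matched random range. Each point is the authors' mean for 1 group, so there are no error bars; the 4 cell cycle genes and the 4 mitochondrial genes are higher in the deleted-labelled sample, and Oasl2 is the 1 interferon-stimulated gene shown that is lower.

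The pathway of the targeted kinase did not stand apart as a list. Among 30 measured IKK and NF-kB components 14 were higher and 16 lower, with a median of -0.038 at percentile 13.1. Ikbke, the gene of the related kinase IKK epsilon, had a ratio of -0.44, and Malt1, the paracaspase gene of the antigen receptor branch, had -0.44. Ltbr, the lymphotoxin beta receptor gene, had -0.34. NF-kB target genes had a median of 0.016 at percentile 75.5, with 13 of 23 higher and 9 lower. Tnf and Bcl3 were higher by 0.30 each, Traf1 had a ratio of -0.30, and Ccnd2 was higher by 0.28 on its brightest probe set with a lowest probe set of -0.40. Apoptosis genes had a median of -0.045 at percentile 9.91. Apart from Birc5, also a cell cycle gene, its largest ratios were -0.42 for the proapoptotic gene Bcl2l11, whose probe sets ran up to 0.040, -0.38 for Pmaip1 and -0.27 for the death receptor gene Fas.

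Other B cell groups also stayed inside their matched random ranges. Immature and transitional markers had a median of -0.068 over 13 members, with Siglecg at -0.21, Cd72 at -0.14 and Lef1 at 0.19. The immature cell marker Cd93, picked after its value was seen, was higher by 0.059. Bone marrow precursor markers had a median of 0.12 over 6 members, led by the receptor gene Flt3 at 0.44, and also held Spn at 0.18, whose lowest probe set was -0.19. B-1 cell markers had a median of 0 and a mean of -0.044 over 7 members, with Zbtb32 at -0.50, Ptpn22 at -0.23 and Cd5 at 0.25. Notch pathway genes had a median of -0.083 over 18 members, 15 of them lower, with Dtx1 at -0.44 on its brightest probe set and 0.031 on another, Jag2 at -0.40, Hes5 at -0.34 and Dll4 at -0.23. Chemokine receptor, adhesion and migration genes had a median of -0.063 over 23 members, 18 of them lower, with S1pr1 at -0.45, Ccr9 at -0.23 and Cxcr4 at -0.21. Antigen presentation genes of MHC class II had a median of -0.040 over 12 members, with H2-Ea at -0.38, Cd74 at -0.10 and H2-Aa at -0.082, which was 0.012 after centring. Their transactivator gene Ciita had 0.29 on its brightest probe set and -0.65 on its lowest.

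Among markers of other cells that a sort can hold, none of the lists with at least 5 measured members lay outside its matched random range. The level filter leaves out S100a8 and S100a9 and most erythroid markers; without it the myeloid median was -0.14 at percentile 4.61 and the erythroid median 0 at percentile 74.2. T cell markers had a median of -0.12 over 12 members, with Lat at 0.41, Cd3e at -0.27 and Cd6 at -0.26. Myeloid markers had a median of -0.14 over 11 members, with Lyz1 at 0.59, Lyz2 at 0.38, Cd68 at -0.31 and Ngp at -0.29. Dendritic cell markers had a median of -0.044 and a mean of 0.054 over 6 members, with Bst2 at 0.37 and Zbtb46 at -0.17. Platelet markers had a median of -0.035 over 5 members, with Treml1 at -0.24, Gp9 at -0.12, Mpl at 0.046 and Itga2b at -0.035, which was above 0 under all 3 scaling alternatives. Stromal and endothelial markers had a median of -0.13 over 5 members, with Vim at -0.23, Sparc at -0.14, Acta2 at -0.13 and Kdr at 0.054. NK cell and erythroid markers had only 3 and 4 measured members, too few to place, with medians of -0.20 and 0.15. Among them Prf1 had -0.29, Klrd1 0.24, Klrb1c -0.20, Eraf 0.31, Gata1 0.26, Car2 -0.094 and Tfrc 0.036. The lowest measured probe set of Tfrc was -0.15.

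General cell maintenance genes lay close to 0. Housekeeping genes had a median of -0.021 over 12 members, with Hmbs at 0.20, Tbp at -0.15, Ubc at -0.15 and Ywhaz at -0.13. The highest measured probe set of Ywhaz was 0.0024. Ribosomal protein genes had a median of -0.019 over 20 members, with Rps6 at 0.25 and Rpl22 at 0.051. Their members Rps24 at -0.068 and Rplp0 at -0.063 were above 0 after centring. Immediate early and heat shock genes, which can respond to handling, had a median of -0.022 over 20 members, with Hsph1 at -0.42, Btg2 at -0.40, Dusp1 at 0.24 and Egr1 at 0.23. The 3′ minus 5′ log2 difference, a measure of RNA integrity on these arrays, was 0.36 in the control and 0.34 in the deleted-labelled sample for Actb, and -0.098 and 0.027 for Gapdh. The same difference for the bacterial poly-A spike-ins, which are added to RNA before labelling, was larger in the deleted-labelled sample for 8 of 8 probe set pairs, by a median of 0.22 (0.051 to 0.56). These pairs cover only the transcripts dap, lys, phe and thr, each on more than 1 pair, so they are not independent. Of the 24 lists with at least 5 measured members, 3 lay above and 3 below the matched random range. By chance 1.2 would be expected if the lists, and the genes within each, varied independently. Co-regulated genes do not, so 1.2 is not a fair chance level for these lists. The other 18 had medians between -0.14 and 0.12, with signs that depend on the scaling. Centring, which adds the same amount to every ratio, turned the sign of 12 of these 18, quantile normalization of 4 and loess of 3.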

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

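The tests on erythroid precursors, on the number of marginal zone cells, on the share of B cells and on Cd19 alleles were chosen after the results were seen. The loess correction was planned before the data were examined, but the patterns it was applied to here were picked from the results.

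The bacterial hybridization spike-ins bioB, bioC and bioD, which no comparison used, were higher in the deleted-labelled sample on 14 of 14 probe sets, with a median log2 ratio of 0.31 (0.11 to 0.50). Several of these probe sets cover the same spike-in. The cre spike-in had a median of 0.066, with 3 of 4 probe sets higher.

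Cell cycle genes had a median log2 ratio of 0.48 in the deleted-labelled sample. An intensity trend between the samples is argued against, since the median was 0.51 after loess correction. Cycling erythroid precursors in the sorted fraction as the whole source are argued against by the low levels of 11 non-globin erythroid markers. These were taken without the level filter and left out Gata1, Car2 and Tfrc, which had ratios of 0.26, -0.094 and 0.036. Log2 levels of the 11 were at most 4.75 in the deleted-labelled sample, and 10 of them lay below its median. Their median ratio was 0 (SD 0.20), but ratios at such levels say little. A smaller amount of red cell RNA stays open, with measured globin ratios of 1.05 and 2.35 at levels up to 8.16 and higher values of Bpgm (0.36 to 0.43) and Slc14a1 (0.57 to 0.86), although a sort for B220 and IgM would remove most such cells. A difference due to the genotype stays open and untested, as does unequal labelling. Poly-A spike-in 3′ minus 5′ differences were larger in that sample by a median of 0.22. Chuk transcript levels did not bear out the label, and whether the probes can check it is unknown.

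Marginal zone markers had a median log2 ratio of -0.22. The median was -0.19 after loess correction, which argues against an intensity trend as the whole cause. Fewer marginal zone B cells in the IgM-high sort may underlie the difference, but no value here bears on it: that 8 of the 9 measured members in no other list (88.9%) were lower restates the pattern. A lower level per cell would give the same count, so these explanations cannot be told apart in sorted bulk RNA. Either would be a difference between the labelled groups, on 1 sample each, and a genotype effect stays untested. The labels do not settle how many Cre copies each group carried. Chuk deletion therefore cannot be told apart from an unequal number of Cre copies or intact Cd19 alleles, for this list or any other.

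Cd19 had a log2 ratio of -0.87 on its 1 probe set. A lower share of B cells is argued against by the other 25 measured members of the B cell identity and receptor list. On their brightest probe sets they had a median of -0.10 (SD 0.088, lowest -0.29). Over all their measured probe sets the ratios ran more widely, from -0.77 (Vav2) to 0.25 (Pik3cd). Unequal numbers of Cd19 alleles disrupted by the Cre knock-in could give such a ratio of -0.87, and the labels do not settle how many Cre copies each group carried. This cannot be told apart from an effect of Chuk deletion on Cd19, with 1 probe set and no replicate columns.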

How the results depend on the processing

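All alternatives here were planned before the data were examined. All 6 lists outside the matched random range kept that call under the 8 alternatives able to change it (48 of 48 combinations); centring adds 0.094 to every ratio and the authors' deposited fold changes are the same values, so neither can. Their medians over all alternatives were 0.19 to 0.57 for cell cycle genes, 0.11 to 0.24 for interferon-stimulated genes, 0.095 to 0.21 for mitochondrial respiration, -0.23 to -0.13 for marginal zone markers, -0.15 to -0.0081 for B cell identity and receptor genes and -0.26 to -0.096 for germinal centre and plasma cell genes. The 3 Chuk probe sets stayed higher in the deleted-labelled sample under each alternative run on them. The counts of 9 probe sets higher and 25 lower moved most. They were 12 and 12 after median centring, 10 and 20 after quantile normalization or loess, and 13 and 37 without a filter. A pseudocount of 16 gave 2 and 13 and one of 64 gave 2 and 5, since adding a constant shrinks the ratios of dim probe sets. The filter at percentile 75 gave 2 and 10, as fewer probe sets entered. Thresholds of 1.5-fold and 3-fold gave 103 and 301, and 1 and 1. With 1 probe set per gene the counts were 7 and 8. Of 520 values of 130 named genes other than Chuk under quantile normalization, loess and the pseudocounts, 399 moved by at most 0.1, 119 moved by more without changing sign (46 with the pseudocount of 16 and 73 with 64), and 2 changed sign. Signs changed for H2-Aa (0.012), Rplp0 (0.031) and Rps24 (0.026) after centring, and Itga2b after centring (0.059), quantile normalization (0.021) and loess (0.025), for which the cause was not tested. Among the 18 other lists with at least 5 measured members 2 values crossed the range, Notch genes after quantile normalization (-0.067, percentile 2.45) and immature markers with the mean of probe sets (-0.13, percentile 1.28). The erythroid list, with too few members to place, went from percentile 97.2 to 97.6 without cross-hybridizing probe sets. No paired analysis was possible because the data hold 1 mean per group with no replicate columns, so limma with a block, leaving out replicates and camera were not run. Signals near the sample median limit the ratios of dim genes.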

Other observations

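The families below, the probe set comparison, the identical values and the transcripts of Xist, Y-linked genes, Bpgm and Slc14a1 were looked at after the data were seen.

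Besides the fixed lists, 170 gene families sharing a symbol stem and at least 8 measured members were placed in the same way. Some share members with those lists, as Mcm does with the cell cycle list and Ndufa with the mitochondrial list. The placement of such families partly restates those lists. Of the 170 families, 22 lay above and 4 below the matched random range. By chance 8.5 would be expected outside it if families, and the genes within each, varied independently, which co-regulated genes do not. The families above every matched random list included the mitochondrial ribosomal proteins, with 44 of 48 large subunit genes (Mrpl) higher at a median log2 ratio of 0.18 and 26 of 29 small subunit genes (Mrps) higher at 0.18. Of the others above every list, complex I accessory subunits (Ndufa) were higher in 13 of 14 cases, with a median of 0.15, and inner membrane import components (Timm) in 12 of 14, with a median of 0.18. Coenzyme Q synthesis genes (Coq) were higher in 11 of 11 cases, with a median of 0.23, and the Mcm stem, which includes the replicative helicase, in 8 of 10, with a median of 0.21. Translation initiation factors (Eif) had 37 of 50 higher and a median of 0.074. The lowest percentiles were those of the Kmt stem of histone methyltransferases, with 6 of 8 lower at a median of -0.17, and the Arid stem of chromatin-associated DNA-binding proteins, with 6 of 9 lower at -0.18. The medians of these families kept their sign under centring, quantile normalization and loess, although centring added 0.094 to each, which left Kmt at -0.071 and Arid at -0.085 and put Eif at 0.17, Ndufa at 0.24 and Mrpl at 0.27, whereas the zinc finger stem Zfp, also below the range at -0.022, turned positive under all 3. In the same sample measured globin probe sets were higher by 1.05 and 2.35, and S100a8 and S100a9 were lower by at least 4.32-fold and at least 2.92-fold. The poly-A spike-in 3′ minus 5′ difference was larger there for 8 of 8 pairs, by a median of 0.22. The bioB, bioC and bioD spike-ins were higher by a median of 0.31. Whether unequal labelling shifted these families was not tested.

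Probe sets of one gene often differed. Of 4823 genes with several measured probe sets, 2963 had a lower mean ratio on the others than on the brightest, with a median difference of -0.050. Of the 25 probe sets at least 2-fold lower, 12 from 10 genes were not the brightest of their gene, against 0 of the 9 higher ones. The chromatin regulator genes Ash1l and Bptf had 0.017 and -0.082 on the brightest probe set against -1.05 and -1.04 on another. The splicing regulator gene Mbnl1 had -0.11 against -1.16, and Herc6 had 0.24 against -1.19.

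Identical values in both samples were found for 2615 probe sets (5.81%), where the density of ratios within 0.01 of 0 would give 0.304 at the precision of the values. Of these, 678 were measured. Xist was high in both samples, with 3 probe sets at ratios of -0.45 to -0.19 and a level up to 11.3 in the deleted-labelled sample. The Y-linked genes Ddx3y and Eif2s3y were below the sample medians in both, with log2 levels up to 2.90 in the deleted-labelled sample. The red cell enzyme gene Bpgm was higher by 0.36 to 0.43 and the urea transporter gene Slc14a1 by 0.57 to 0.86.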
